A study of Mus musculus with 12 samples.

How the data were processed

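RNA of the whole colon of 12 mice was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols, which give no batch, slide or date. Groups were taken from the genotype and treatment given for each sample, and the replicate numbers only name the mice of a group. The mice of each group were separate animals. The deposited table held log2 values of 31693 probe sets on 12 arrays; the software, background correction and normalization that the authors used are not given in the sources used here. The values ran from -4.83 to 5.47 and the median of each probe set over the 12 arrays was 0 to within 5e-07, so the table was centred per probe set and levels of different genes cannot be compared. The log base and the direction are not stated and stay unknown: base 2 was assumed, with larger values for more RNA, while the centring follows from the values. The column medians were 0.0576, 0.0999 and 0.0946 in wild-type water 1 to 3, 0.0784, 0.000299 and -0.00104 in wild-type DSS, -0.00315, -0.0310 and -0.0438 in Parp1-/- water and 0.000797, -0.0204 and -0.00781 in Parp1-/- DSS. No scanner files were used here, so signal over background is unknown. No 2 arrays held identical values.

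Probe sets were named from the GEO annotation of the platform. Of the 31693, 22586 had 1 gene symbol, 1756 several and 7351 none, and 22406 of those with 1 symbol had an entrez ID found in a RefSeq gene table of assembly GRCm38.p6. That table served for names and for which genes neighbour each other; the build behind the array is not given in the sources used here, so no coordinates are printed. Probe sets with several symbols or none were tested apart and named no gene. The 21314 genes had 1 probe set in 20283 cases and more in 1031. The plan was to represent a gene by its probe set with the highest mean, but the centring removes brightness and leaves that choice to deviations between arrays. The mean of a gene's probe sets, planned as an alternative, was therefore used in the results, and the rule as planned was run as an alternative. The planned filter on dim probe sets was not run for the same reason, and the planned log2(value + 16) did not apply to values already on a log scale.

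Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes) in 1 model of the 4 groups over all 12 arrays, and contrasts gave DSS against water in each genotype, Parp1-/- against wild type in each treatment, their average and the difference of the DSS responses. P-values were adjusted by Benjamini-Hochberg over all genes, and a gene was called at an adjusted p under 0.05. Errors of log2 differences are standard errors of the model. A total of 37 gene lists for cell types and pathways of the colon were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, with camera at an estimated correlation and with fry. The lists held 750 entries, of which 677 were measured. In each list described, the median, the mean and the camera test had the same sign. Means of lists per array and Parp1 were compared by two-sided exact permutation tests. Correlations of DSS responses were taken across genes. The housekeeping genes, 17 of 20 measured, and the 1056 receptor genes were chosen after seeing the data, to describe the arrays that stood apart. Tables were read with Python 3.11.15 and pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

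The groups, the tests, the lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where another time is stated. For each contrast the rule named Parp1, the 8 called genes with the largest change in each direction among those whose groups did not overlap (for the average and the difference of responses, among all called genes), the 5 genes of smallest p where fewer than 5 were called, and, for each list described, up to 4 called members with the largest change or otherwise the 2 of smallest p. Predicted gene models, clones, small RNA genes, receptor genes of smell and immune receptor segments were passed over, and a gene named in 1 contrast was given in others where useful.

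The alternatives were quantile normalization between arrays, array medians set equal, every probe set tested on its own, the probe set with the highest mean, eBayes with trend and robust options, array weights, only the arrays of the groups compared, a change of at least 1.5-fold, an adjusted p under 0.01 and leaving out each array in turn. Alternatives chosen after seeing the data were the receptor median of each array as a covariate and a fit of 8 arrays without wild-type water and wild-type DSS 1. The receptor median did not overlap between the wild-type and Parp1-/- water arrays. The covariate fit therefore cannot separate it from the genotype difference in water. The model was tested on simulated data over 21314 genes, with values drawn separately for each gene from its real residual spread, taken as equal in all groups. For DSS in Parp1-/- mice it recovered 8%, 48%, 82% and 98% of genes changed by log2 0.5, 1, 2 and 3, with 14 false calls among 21114 unchanged genes. For genotype in water it recovered 0%, 28%, 94% and 98%, with 12 false calls. The simulation left out differences that many genes of an array share and unequal spread between groups. Its false calls therefore cannot be carried over to the real comparisons.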

Results

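The study examined how the colon of mice without Parp1, the enzyme that attaches ADP-ribose chains to proteins at broken DNA, differed from that of wild-type mice at rest and after chemical injury. Injury was caused by dextran sulfate sodium (DSS), a sulfated polysaccharide that damages the colon lining and brings on colitis when mice drink it. RNA from the whole colon of 12 mice was measured on 12 Affymetrix arrays, 1 per mouse, in 4 groups of 3 mice: wild type in water, wild type in 4% DSS for 7 days, Parp1-/- in water and Parp1-/- in DSS. The values covered 21314 genes and were log2 values centred on each probe set's median over the 12 arrays, so a gene can be compared between arrays and genes cannot be ranked by brightness. The log base and the direction of the scale are not given in the sources used here, and base 2 with larger values for more RNA was assumed. The number of arrays limits the precision of every comparison. A gene was called where the adjusted p of limma was under 0.05.

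Parp1 itself averaged 0.43 ± 0.55 (SD, n = 6) in wild-type mice and -0.07 ± 0.09 (SD, n = 6) in Parp1-/- mice, and a two-sided exact permutation test of this difference gave p = 0.0498 over 924 permutations. In wild-type water the 3 arrays had Parp1 at -0.41, 1.15 and 0.53, and in wild-type DSS at 0.01, 0.51 and 0.77. In Parp1-/- water it was at -0.03, -0.08 and -0.01, and in Parp1-/- DSS at -0.22, -0.09 and 0.03. The array labelled wild-type water 1 thus had Parp1 below every Parp1-/- array, and the array labelled wild-type DSS 1 lay within the Parp1-/- range, while 4 of the 6 wild-type arrays lay above all 6 Parp1-/- arrays. Housekeeping genes, described below, averaged -1.83 in wild-type water 1 and -0.97 in wild-type DSS 1. In every wild-type array Parp1 lay above the housekeeping mean of that array, and in every Parp1-/- array below it. The housekeeping genes were chosen after seeing the data, to describe the arrays that stood apart. In wild-type water 1 the median of all probe sets, 0.0576, also lay above their mean. A position of Parp1 above that mean therefore says little there, and it leaves the label of wild-type water 1 undecided. Where the probes of this gene lie relative to the altered part of the locus is not given in the sources used here, so Parp1 is a weak check of the labels.

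Another set of genes separated 4 arrays from the other 8. The mean of 17 housekeeping genes, which are active in nearly all cells, was at -1.83, -1.11 and -1.30 in the arrays labelled wild-type water 1, 2 and 3 and at -0.97 in wild-type DSS 1, against 0.01 to 0.35 in the remaining 8 arrays. The median of 1056 olfactory and vomeronasal receptor genes, whose products serve smell, was at 0.42, 0.38, 0.39 and 0.38 in those 4 arrays and between -0.12 and 0.05 in the others. The SD over all probe sets was 0.871, 0.666, 0.723 and 0.833 in the 4 arrays and 0.256 to 0.394 in the others. These 4 arrays include every wild-type water array, so each comparison with that group holds this difference. Smooth muscle genes set another 3 arrays apart: their mean was 2.26 and 2.16 in Parp1-/- water 2 and 3 and 2.28 in Parp1-/- DSS 1, against -0.35 to 0.04 in the other 9 arrays.

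**Figure D1:**
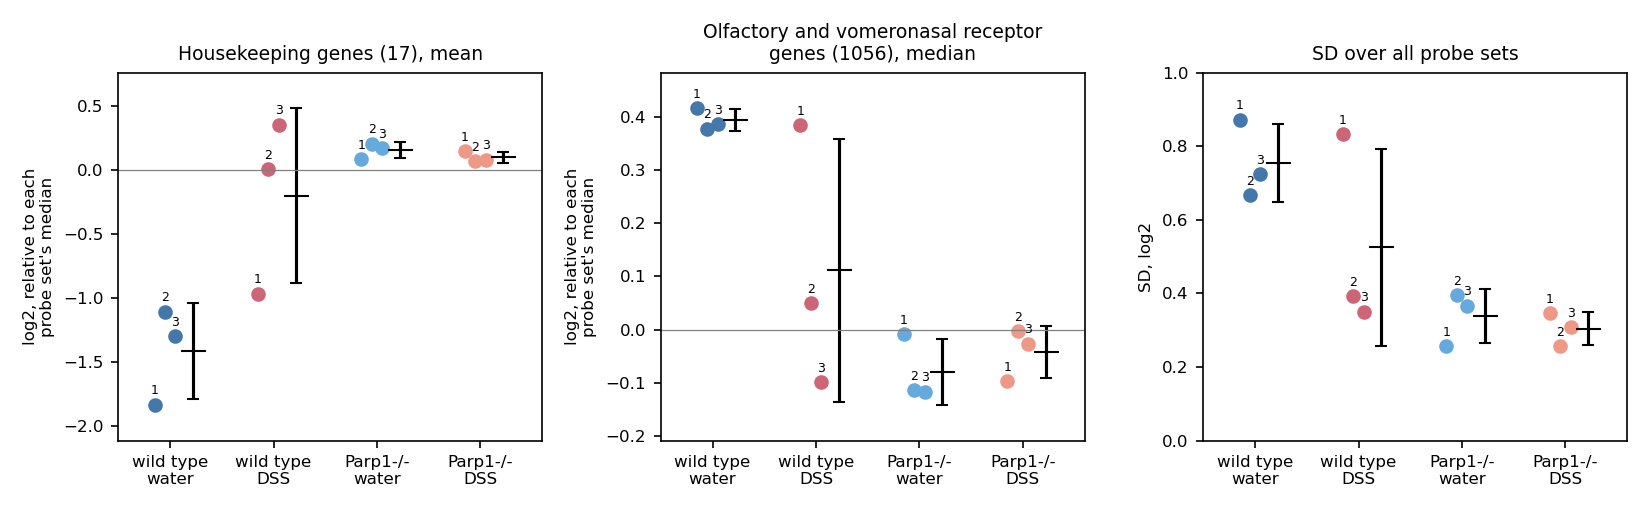
Each point is 1 array, labelled by its replicate number, with the mean ± SD of each group of 3, for the mean of 17 housekeeping genes, the median of 1056 receptor genes (both log2, relative to the median of the 12 arrays) and the SD over all probe sets. The 3 wild-type water arrays and wild-type DSS 1 have housekeeping means from -1.83 to -0.97, below all other arrays.

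In wild-type mice, members of the inflammatory, antimicrobial and mucus lists were higher after DSS, with list means of 1.38, 1.45 and 1.18. The housekeeping genes had a mean of 1.21 in the same comparison, so the mucus list rose no more than they did. None of these lists held its camera call with an estimated correlation, where the smallest adjusted p of any list was 0.543. Clca4b, a member of a family of chloride channel regulators, rose by log2 5.67 ± 0.39 (SE, n = 3 mice per group), with a limma adjusted p of 3.78e-05. Il1b, the cytokine interleukin-1 beta, rose by 4.34 ± 0.74, Nos2, the inducible nitric oxide synthase, by 4.31 ± 0.37, and the antimicrobial lectins Reg3b and Reg3g by 4.26 ± 0.68 and 3.99 ± 0.47. Lilrb4a, an inhibitory receptor of myeloid cells, rose by 4.20 ± 0.76, the acute-phase gene Saa3 by 4.10 ± 0.82 and the chemokine Ccl3 by 4.02 ± 0.92. Psme2, a subunit of a proteasome activator, had the largest fall among the genes selected by the naming rule, at -2.12 ± 0.25, followed by the elastase Cela1 at -1.93 ± 0.51 and Bcr, a regulator of small GTPases, at -1.80 ± 0.29. Nt5dc2, Srgap1, Tpcn1, Pramel22 and Epn3 fell, at -1.76, -1.74, -1.69, -1.64 and -1.64. By the naming rule, the 3 DSS arrays of each of these 16 genes lay wholly on 1 side of the 3 water arrays. Parp1 was at 0.00 ± 0.33.

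Among the inflammatory cytokines and chemokines, 19 of 23 measured members were above 0, with a mean of 1.38. Over all genes tested 8 of them rose, including Il1a by 3.91 and the interferon-induced chemokine Cxcl10 by 3.42, and 9 rose and 1 fell when adjusted over the list alone. Of the neutrophil and inflammatory monocyte markers all 18 were above 0, with a mean of 1.41, and 6 rose, among them Ly6g by 3.17, the chemokine receptor Cxcr2 by 2.11, Retnlg by 2.02 and the neutrophil collagenase Mmp8 by 1.85. Adjusted over the list alone, 13 rose. In the antimicrobial list 9 of 21 members rose and 1 fell (11 and 1 adjusted over the list alone), with a mean of 1.45. Interferon response genes had 5 of 22 members higher and 7 adjusted over the list alone, with a mean of 0.71, including the GTPase Iigp1 at 1.64, Ifit1 at 1.61 and Oasl2 at 1.55. Wild-type DSS 1, at -0.079 for the interferon list, lay within the range of the water arrays. A two-sided exact permutation test of this list gave p = 0.2, where the smallest possible is 0.1. Epithelial repair genes had 5 of 14 higher and 7 adjusted over the list alone, with a mean of 1.06, including the collagen-binding integrin Itga2 at 3.13, Anxa3 at 2.37, the urokinase receptor Plaur at 2.16 and Sprr1a at 1.82. Extracellular matrix genes had 3 of 25 higher and 4 adjusted over the list alone, with a mean of 0.77, including the metalloproteinases Mmp13 at 2.76 and Mmp10 at 2.75.

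In the same comparison, 9 of 19 members of the goblet cell and mucus list rose and 12 adjusted over the list alone, with a mean of 1.18, among them the mucins Muc13 by 2.46 ± 0.19 and Muc2 by 2.10 ± 0.16, the kallikrein Klk1 by 2.37 ± 0.17 and Agr2, which helps mucin folding, by 1.95. Colonocyte genes had 7 of 24 members higher and 9 adjusted over the list alone, with a mean of 0.77, including the carbonic anhydrases Car4 at 2.18 and Car1 at 2.09, the microvillus protein Vil1 at 1.83 and the keratin Krt20 at 1.74. Respiratory chain genes had 8 of 25 members higher and 9 adjusted over the list alone, also with a mean of 0.77, including Uqcrc2 at 1.87 and Sdha at 1.72. Wild-type DSS 1, at -1.05 for the colonocyte list and -1.13 for the respiratory chain list, lay within the range of the water arrays, and two-sided exact permutation tests gave p = 0.3 for each of these lists, where 3 against 3 mice cannot go below 0.1. Beside these, the housekeeping genes had a median difference of 1.27 with 10 of 17 called higher, and the receptor genes -0.33 with 99 of 1056 called lower. Both kept their sign after quantile normalization, at 0.66 and -0.25.

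Over all genes, limma called 1894 higher and 887 lower, and 23.6% of genes had groups that did not overlap, against 10% by chance. The camera test called 20 of 37 lists higher and 1 lower, with adjusted p from 4.58e-09 for goblet cells to 0.00691 for extracellular matrix among the lists described here. None held with an estimated correlation: the goblet, antimicrobial and repair lists had adjusted p = 0.543 with an estimated correlation, and the other 6 described here adjusted p = 0.59 with an estimated correlation. Fry called 6 lists, among them 4 of the 9 described here, namely goblet cells, the antimicrobial list, repair and inflammatory cytokines. Clca4b, Il1b, Nos2, Reg3g, Psme2, Bcr, Muc13, Muc2, Klk1, Car1, Uqcrc2 and Itga2 were called in the same direction under every alternative run for them, which for Muc2 did not include every probe set on its own. The count was 6865 without wild-type DSS 1, 1211 without wild-type DSS 2, 1712 without wild-type DSS 3 and 641 when only these 6 arrays were fitted, and quantile normalization gave 218 higher and 14 lower. It was 2209 without the array labelled wild-type water 1. Of 44 called genes considered by name, 10, 8 and 15 were not called without the arrays labelled wild-type water 1, 2 and 3, and 1, 17 and 7 without wild-type DSS 1, 2 and 3, the 17 including Ccl3, Il1a, Cxcl10, Ly6g and Mmp13. After quantile normalization 31 of the 44 were not called, among them Reg3b, Lilrb4a, Saa3, Cela1, Agr2, Car4 and Krt20. With the receptor median of each array as a covariate, a fit chosen after seeing the data, 1172 genes were higher and 1059 lower, and 986 of the 2781 calls were kept. In that fit 15 of the 44 were not called, the colonocyte and respiratory chain lists turned to -0.007 and -0.07, and the extracellular matrix and interferon lists were not called. With only these 6 arrays fitted, 13 of the 44 were not called.

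**Figure D2:**
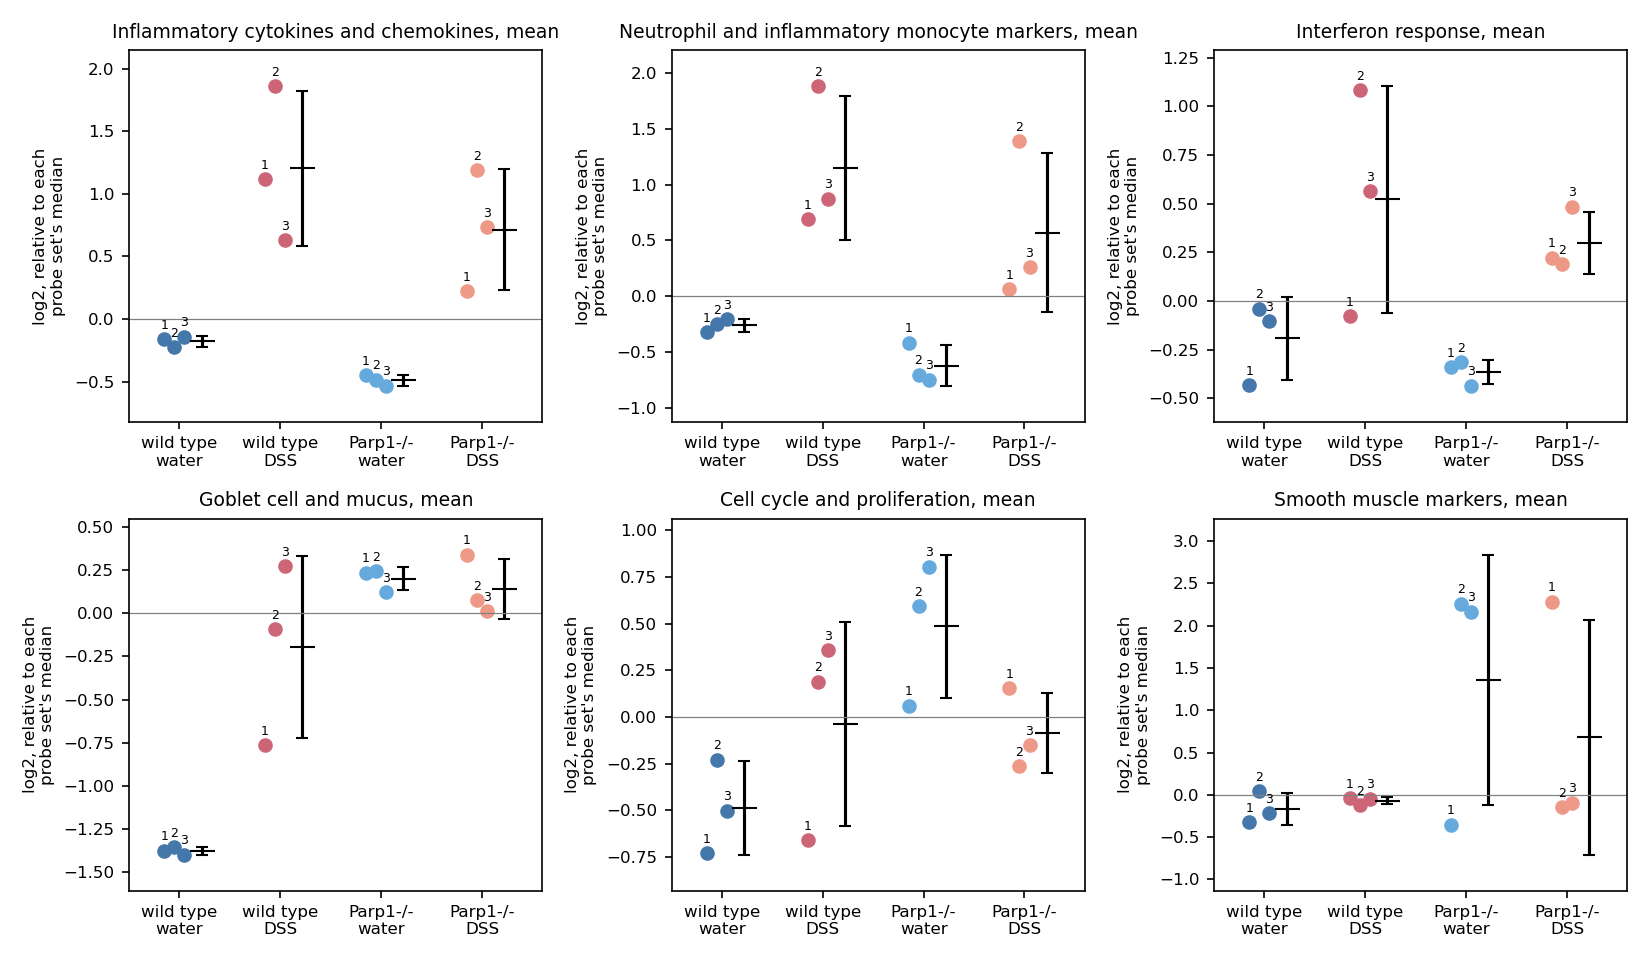
Mean log2 value of the measured members of 6 gene lists in each array, relative to the median of the 12 arrays, with points for single mice and the mean ± SD of each group of 3. The inflammatory list lies between 0.22 and 1.86 in the DSS arrays of both genotypes and between -0.53 and -0.14 in the water arrays, and the smooth muscle list is above 2 only in Parp1-/- water 2 and 3 and Parp1-/- DSS 1.

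In Parp1-/- mice DSS raised Clca4b by log2 4.99 ± 0.39 (SE, n = 3 mice per group), with a limma adjusted p of 0.00108, and Nos2 by 3.17 ± 0.37, with an adjusted p of 0.0341. Both were also called in wild-type mice. The genes with the next smallest p were not called: the protease inhibitor Slpi was at 4.00 ± 0.54, the retinoic acid-forming enzyme Aldh1a3 at 3.79 ± 0.54 and the clock transcription factor Npas2 at 1.73 ± 0.23. As groups, inflammatory genes rose: 21 of 23 cytokines and chemokines were above 0, with a mean of 1.20 and a camera adjusted p of 4.69e-19. Epithelial repair genes rose as a group too, with 13 of 14 above 0, a mean of 0.64 and an adjusted p of 9.65e-09.

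None of the 23 inflammatory members was called over all genes and 6 rose when adjusted over the list alone. Il1b was at 3.41 ± 0.74 and the neutrophil chemokine Cxcl5 at 2.46. In the repair list 4 of 14 rose adjusted over the list alone, with Plaur at 1.81 and Sprr1a at 1.23, neither called over all genes. These 2 lists held their call at adjusted p = 0.0352 with an estimated correlation, and no other list did in any comparison. Fry called neither, at an adjusted p of 0.0632 for each, its smallest here. The neutrophil list had 17 of 18 members above 0, a mean of 1.19 and 2 members higher adjusted over the list alone, with Ly6g at 4.11 ± 0.86 and Ly6c2 at 2.16. The interferon list had all 22 above 0, a mean of 0.66 and 4 higher adjusted over the list alone, with Oasl2 at 1.82 and Ifit1 at 1.55. The antimicrobial list had 17 of 21 above 0, a mean of 0.75, 1 member called over all genes (Nos2), and 6 higher and 1 lower adjusted over the list alone. Camera called these 3 lists higher, at adjusted p of 8.86e-19, 3.32e-17 and 1.14e-07, and each had adjusted p = 0.127 with an estimated correlation. NF-kappaB targets were called higher, with 15 of 18 above 0, a mean of 0.50, Rel at 1.92, the inhibitor Tnfaip3 at 1.20 and 1 member higher adjusted over the list alone, and adjusted p = 0.159 with an estimated correlation. Colonocyte genes were called higher, with a mean of 0.32, the proton pump Atp12a at 3.19, the sodium channel subunit Scnn1b at 0.94 and 3 of 24 higher adjusted over the list alone, and adjusted p = 0.502 with an estimated correlation. The colonocyte list mean was 0.50, -0.15 and -0.23 in the water arrays and 0.51, 0.11 and 0.45 in the DSS arrays. A two-sided exact permutation test of it gave p = 0.3.

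Lists that fell included cell cycle genes, of which none of 23 was above 0, with a mean of -0.57, the proliferation marker Mki67 at -0.86 and the replication helicase subunit Mcm2 at -0.70. Camera gave 2.43e-15, and adjusted p = 0.179 with an estimated correlation. The cell cycle mean was 0.06, 0.59 and 0.80 in the water arrays and 0.15, -0.26 and -0.15 in the DSS arrays, so in each group it was highest in the arrays with high smooth muscle genes. Stem cell markers had 2 of 13 above 0 and a mean of -0.32, with Lgr5 at -0.61 and Smoc2 at -0.96, and adjusted p = 0.206 with an estimated correlation. Respiratory chain genes had 3 of 25 above 0 and a mean of -0.31, with Ndufs1 at -0.66 and Ndufa4 at -1.07, and adjusted p = 0.483 with an estimated correlation. Endothelium markers had 1 of 16 above 0 and a mean of -0.29, also with adjusted p = 0.483 with an estimated correlation. The endothelium mean was -0.31, 0.88 and 0.59 in the water arrays and 0.35, 0.10 and -0.15 in the DSS arrays. In each group it too was highest in the arrays with high smooth muscle genes. Smooth muscle genes had 1 of 19 above 0 and a mean of -0.68, with Tagln at -1.21 ± 1.05 and Smtn at -0.41, and adjusted p = 0.502 with an estimated correlation. Their mean was -0.35, 2.26 and 2.16 in the water arrays and 2.28, -0.15 and -0.09 in the DSS arrays. In none of these 5 lists was a member called, over all genes or adjusted over the list alone. Parp1 was at -0.05.

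Over all genes, limma called 2 genes higher and 0 lower, 609 genes had an unadjusted p under 0.05, and 12.5% had groups that did not overlap, against 10% by chance. Those 609 were less than a share of 0.05 of all genes, the share that chance alone would give on average. Camera called 13 of 37 lists higher and 9 lower. Clca4b was called under every alternative run for it, while Nos2 had adjusted p of 0.289 without Parp1-/- water 2, 0.197 without Parp1-/- water 3, 0.119 without Parp1-/- DSS 1, 0.259 without Parp1-/- DSS 3 and 0.0527 with only these 6 arrays fitted. The count was 11, 1 and 1 without Parp1-/- water 1, 2 and 3 and 1, 7 and 1 without Parp1-/- DSS 1, 2 and 3. It was 71 higher and 14 lower after quantile normalization, and 12 higher and 1 lower with only the 8 arrays other than wild-type water and wild-type DSS 1. The smooth muscle call was lost, with adjusted p of 0.151, 0.143, 0.108 and 0.106, without Parp1-/- water 2, Parp1-/- water 3, Parp1-/- DSS 2 and Parp1-/- DSS 3, and that of endothelium, at 0.365, without Parp1-/- water 2. Quantile normalization lost both, and only these 6 arrays fitted the smooth muscle call.

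The genotypes were compared in water to ask how the uninjured colon differs without Parp1. Adamdec1, a metalloproteinase of the gut mucosa, was higher in Parp1-/- mice by log2 3.83 ± 0.73 (SE, n = 3 mice per group), with a limma adjusted p of 0.00406. Rabggtb, a subunit of the enzyme that prenylates Rab proteins, was higher by 3.44, Atad1, an ATPase of the mitochondrial outer membrane, by 3.34 ± 0.30, the SUMO protease Senp6 by 3.26 ± 0.28, and Gstk1, Ndufb9, Postn and Rep15 by 3.31, 3.31, 3.26 and 3.24. Pramel16, Bcr and Eif4a3l1 were lower, at -1.68, -1.60 and -1.54, and so were Myod1, Trim15, Mrgpra2b, Pramel22 and H2ac1, at -1.51, -1.51, -1.50, -1.46 and -1.45. By the naming rule, the 2 groups of each of these 16 genes did not overlap. Parp1 was at -0.47 and not called. Without the array labelled wild-type water 1, the wild-type array with the lowest Parp1, Parp1 was called lower, at -0.88 with an adjusted p of 0.0297, and without wild-type water 2 it was at -0.10. Array weights, whose estimation did not converge, also called it lower, in each genotype comparison.

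In the goblet cell list 15 of 19 members were higher in Parp1-/- mice and 16 adjusted over the list alone, with a mean of 1.57, among them Klk1 at 2.66, Muc13 at 2.46, Muc2 at 2.33 and Agr2 at 2.13. Respiratory chain genes had 20 of 25 higher and 21 adjusted over the list alone, with a mean of 1.52, including Cox4i1 at 3.02, Ndufa4 at 2.49 and Sdha at 2.41. Fatty acid oxidation genes had 15 of 21 higher by either adjustment, being 15 adjusted over the list alone as well, with a mean of 1.45, including the dehydrogenases Hadh at 2.37 and Acadl at 2.34. Cholesterol synthesis genes had 9 of 16 higher and 12 adjusted over the list alone, with a mean of 1.34, including Hmgcs1 at 3.21 and Insig1 at 2.52. Tight junction and adhesion genes had 13 of 22 higher and 14 adjusted over the list alone, with a mean of 1.12, including the cadherin Cdh17 at 2.30 and Epcam at 2.06. Xenobiotic metabolism genes had 13 of 30 higher, and 17 higher and 1 lower adjusted over the list alone, with a mean of 0.98, including Cyp3a13 at 2.33 and the sulfotransferase Sult1a1 at 1.98. Cell cycle genes had 11 of 23 higher and 12 adjusted over the list alone, with a mean of 0.97, including Cdk1 at 2.25 and Mki67 at 2.02. Squamous epithelium genes were called lower as a list, with a mean of -0.44 and 9 of 19 members lower, such as Sfn at -1.13 and the desmoglein Dsg3 at -1.07. Also lower were T and NK cell markers, with a mean of -0.26 and 4 of 21 lower, such as the T cell receptor component Cd3d at -0.89 and the granzyme Gzma at -0.56. Each had adjusted p = 0.652 with an estimated correlation, 1 member higher, and the same counts adjusted over the list alone. The cytokines Csf2 and Csf3 were lower too, at -0.70 and -0.51. Smooth muscle genes had a mean of 1.53 with 16 of 19 above 0 and 1 called lower, and none adjusted over the list alone. Their mean was -0.35, 2.26 and 2.16 in the Parp1-/- water arrays.

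In the same comparison the housekeeping genes had a median of 1.63, with 14 of 17 called higher, and the receptor genes -0.52, with 392 of 1056 called lower and 1 higher. Both kept their sign under the other scalings, at 1.03 and -0.38 after quantile normalization and at 1.74 and -0.41 with array medians set equal. Setting array medians equal moved the median of all genes from -0.07 to 0.04, the only scaling shift above 0.1 in any comparison. Over all genes, limma called 3813 higher and 2912 lower, and 55.4% of genes had groups that did not overlap, against 10% by chance. Camera called 16 lists higher and 2 lower, at adjusted p from 6.88e-09 for goblet cells to 0.0443 for T cells. None held, with adjusted p = 0.767 with an estimated correlation for smooth muscle and adjusted p = 0.652 with an estimated correlation for the other 9 lists described. Fry called 17 lists, including each of these except smooth muscle. The split was 1773 higher and 446 lower after quantile normalization and 4133 higher and 1654 lower with array medians equal, and with the receptor median of each array as a covariate, a fit chosen after seeing the data, 276 genes were higher and 183 lower, and 227 of the 6725 calls were kept. Without the array labelled wild-type water 1 the count was 5005. It was 2948 without Parp1-/- water 2 and 3029 without Parp1-/- water 3. Of 39 called genes considered by name, 3, 12 and 11 were not called without Parp1-/- water 1, 2 and 3 and 7, 7 and 3 without the arrays labelled wild-type water 1, 2 and 3. With the covariate 25 of the 39 were not called and another 4, Pramel16, Eif4a3l1, Myod1 and Mrgpra2b, changed sign. The cell cycle, cholesterol, fatty acid, tight junction and xenobiotic lists changed sign too, and the respiratory chain, smooth muscle, squamous and T cell lists were not called. As the receptor median did not overlap between the groups compared, losses with the covariate do not show that a difference is absent. Quantile normalization lost 7 of the 39. Klk1, Muc13, Muc2, Agr2, Atad1, Senp6, Bcr and Epcam were called under every alternative run for them. The smooth muscle call was lost without wild-type water 2 (adjusted p 0.056) and 3 (0.0549) and Parp1-/- water 2 (0.118) and 3 (0.123), and the T cell call without the array labelled wild-type water 1 (0.0586), wild-type water 2 (0.0601) and Parp1-/- water 2 (0.0678) and 3 (0.0896). The T cell call was also lost with the probe set rule as planned, with every probe set tested on its own and with only these 6 arrays fitted, and the smooth muscle call with trend and robust options.

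After DSS no gene was called between the genotypes. The genes with the smallest p were the tubulin Tuba1b at log2 -1.16 ± 0.24 (SE, n = 3 mice per group), the adaptor protein Ywhah at -0.93 ± 0.19, the fatty acid synthase Fasn at 1.95 ± 0.43, Aldh1a3 at 2.39 ± 0.54 and the RNA-binding protein Hnrnpk at -1.09 ± 0.25, all with a limma adjusted p of 0.872. As a group, neutrophil and inflammatory monocyte markers were lower in Parp1-/- mice, with 2 of 18 above 0, a mean of -0.58 and a camera adjusted p of 5.51e-06, but adjusted p = 0.697 with an estimated correlation. Mmp8 was at -1.63 ± 0.39 and Ngp at -0.86. The list mean ranged from -0.21 without wild-type DSS 2 to -0.99 without Parp1-/- DSS 2 when each of these 6 arrays was left out in turn, and a two-sided exact permutation test of its mean per array gave p = 0.4, where 3 against 3 mice cannot go below 0.1.

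T and NK cell markers were lower as a group, with 2 of 21 above 0, a mean of -0.26, Gata3 at -0.54 and Gzma at -0.40, and adjusted p = 0.189 with an estimated correlation. The two-sided exact permutation p of the T cell list mean was 0.1, the smallest possible. For the other 7 lists described below the same test gave p between 0.4 and 0.9. Inflammatory cytokines had 7 of 23 above 0 and a mean of -0.49, with Cxcl9 at -2.02 and Cxcl10 at -2.12. Interferon genes had 5 of 22 above 0 and a mean of -0.22, with Iigp1 at -1.39 and Igtp at -0.88. Camera called both lists lower, but each had adjusted p = 0.697 with an estimated correlation. Among the lists called higher were tight junction genes, with 19 of 22 above 0 and a mean of 0.58 (Cldn8 at 1.59, Tjp1 at 1.10), and colonocyte genes with 21 of 24 and a mean of 0.54 (Atp12a at 2.78, Scnn1a at 1.28). Also higher were respiratory chain genes, with 22 of 25 and a mean of 0.44, goblet cell genes with 17 of 19 and a mean of 0.34 (Fcgbp at 0.99), and smooth muscle genes with 18 of 19 and a mean of 0.75, with 2.28 in Parp1-/- DSS 1 against -0.15 and -0.09 in the other 2 Parp1-/- DSS arrays. The calls of these 7 lists were lost, with adjusted p = 0.733 with an estimated correlation for smooth muscle and adjusted p = 0.697 with an estimated correlation for the other 6. In these lists no member was called over all genes, and adjusted over the list alone only 1 neutrophil gene was, lower. The housekeeping genes had a median of 0.33 and the receptor genes -0.17, with the housekeeping mean at -0.97 in wild-type DSS 1 against 0.01 and 0.35 in wild-type DSS 2 and 3. Parp1 was at -0.52 ± 0.33.

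Limma called 0 genes at an adjusted p under 0.05, with 593 at an unadjusted p under 0.05, and 6.55% of genes had groups that did not overlap, against 10% by chance. Those 593 were less than a share of 0.05 of all genes, the share that chance alone would give on average. Array weights, whose estimation did not converge, called 6184 genes, and every other setting with all 12 arrays called none. Camera called 12 lists higher and 4 lower, and fry called none. Without wild-type DSS 1 the calls of the tight junction, colonocyte, goblet and respiratory chain lists were lost, at adjusted p of 0.101, 0.453, 0.359 and 0.648 and means of 0.16, 0.11, 0.05 and 0.05. Without wild-type DSS 2 the inflammatory list was not called, at 0.31, and the interferon list turned to 0.06. Without wild-type DSS 3 limma called 2 genes and the smooth muscle list was not called, at 0.183. Without Parp1-/- DSS 1 the inflammatory list was not called, at 0.544, and smooth muscle turned to -0.05. With the receptor median as a covariate the colonocyte, goblet, tight junction and inflammatory lists were not called and the respiratory chain list turned to -0.022, and after quantile normalization the inflammatory and interferon lists were not called. The inflammatory call was also lost with trend and robust options and with every probe set tested on its own, and the colonocyte, goblet and smooth muscle calls with array weights. With only the 8 arrays other than wild-type water and wild-type DSS 1, the colonocyte, goblet, respiratory chain, tight junction and inflammatory lists were not called.

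Averaged over water and DSS, the transporter Slc37a2 was higher in Parp1-/- mice by log2 2.30 ± 0.57 (SE, n = 6 mice per genotype), with a limma adjusted p of 0.0198. Fasn was higher by 2.18 ± 0.30, with an adjusted p of 0.00197. Rep15, Hint1, Ndufb9, the stearoyl-CoA desaturase Scd1, the pentose phosphate enzyme Pgd and the lysosomal protease Ctsd were higher by 2.20, 2.17, 2.17, 2.08, 2.07 and 2.02. Stfa2l1, a stefin, was lower, at -1.29 ± 0.29, and Pramel16, Vmp1, the Fc receptor Fcgr4, Mmp8, Gpr65, Zfp747 and Ppifos were called lower too, at -1.14 for Pramel16 to -0.87 for Ppifos. Parp1 was at -0.49 and not called. It was called lower, at -0.70 with an adjusted p of 0.0232, without the array labelled wild-type water 1, and was at -0.31 without wild-type water 2.

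In this averaged comparison goblet cell genes had 14 of 19 members higher and 16 adjusted over the list alone, with a mean of 0.96, respiratory chain genes 18 of 25 and 21 with a mean of 0.98, and fatty acid oxidation genes 15 of 21 and 17 with a mean of 0.95, each second count adjusted over the list alone. T cell markers had 5 of 21 lower and 7 adjusted over the list alone, with a mean of -0.26, and neutrophil markers 2 of 18 lower by either adjustment, with a mean of -0.47. Camera called these 5 lists, at adjusted p of 1.42e-08, 3.94e-08, 2.3e-06, 0.00531 and 0.012, but with adjusted p = 0.707 with an estimated correlation for neutrophils and adjusted p = 0.565 with an estimated correlation for the others. Fry called 14 lists, including these except neutrophils. The neutrophil list was not called without wild-type DSS 2, at 0.0872, nor with every probe set tested on its own. With the receptor median as a covariate the respiratory chain and T cell lists were not called and the fatty acid list turned to -0.033. The housekeeping genes had a median of 0.86 and the receptor genes -0.34. Limma called 3196 genes higher and 1605 lower. Quantile normalization gave 1552 and 234, array medians set equal 3485 and 781, and the receptor median as a covariate 12 genes in all. The count was 9133 without wild-type DSS 3, 3074 without wild-type DSS 2, 1967 and 1935 without Parp1-/- water 2 and 3, and 1921, 2904 and 2600 without Parp1-/- DSS 1, 2 and 3. Of the 16 genes named as called, 2, 1 and 1 were not called without the arrays labelled wild-type water 1, 2 and 3, 1, 3 and 0 without wild-type DSS 1, 2 and 3, 1, 5 and 6 without Parp1-/- water 1, 2 and 3, and 5, 1 and 5 without Parp1-/- DSS 1, 2 and 3, Pgd and Pramel16 being among those lost. With the covariate none of the 16 kept its call, 13 keeping their direction and Pgd, Pramel16 and Ppifos changing sign, and quantile normalization lost 5. Without the array labelled wild-type water 1 the count was 3820.

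The difference of the DSS response between genotypes was tested as an interaction. Adamdec1, which rose in wild-type mice by log2 2.66 ± 0.73 and was at -1.98 ± 0.73 in Parp1-/- mice, differed by -4.64 ± 1.03 (SE, n = 3 mice in each of 4 groups). Reg3g rose by 3.99 ± 0.47 in wild-type mice and was at 0.49 ± 0.47 in Parp1-/- mice, a called difference of -3.51 ± 0.66. Slpi went the other way, at 0.54 ± 0.54 in wild-type and 4.00 ± 0.54 in Parp1-/- mice, a called difference of 3.46 ± 0.77. Goblet cell genes had a lower response in Parp1-/- mice, but adjusted p = 0.71 with an estimated correlation, beside a median of -1.35 in the housekeeping genes. They had a list mean of -1.24, none of 19 above 0, 7 called lower and 9 adjusted over the list alone, among them Klk1 at -2.47 ± 0.25 and Muc2 at -2.19 ± 0.22.

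Respiratory chain, cell cycle and fatty acid oxidation genes also had lower mean responses in Parp1-/- mice, at -1.08, -1.02 and -1.01, beside a median of -1.35 in the housekeeping genes. Each of these lists had adjusted p = 0.71 with an estimated correlation. In these, 2 of 25, 4 of 23 and 3 of 21 members were called lower, and 10, 5 and 6 adjusted over the list alone. Among the cell cycle genes Cdk1 was at -2.72 and Mki67 at -1.97. Colonocyte genes had a mean of -0.45, 3 of 24 lower and 5 adjusted over the list alone, with Car1 at -2.04 ± 0.22, and the antimicrobial list a mean of -0.71, 3 of 21 lower and 1 higher, and 6 and 1 adjusted over the list alone. Squamous epithelium genes had a mean of 0.37, with 15 of 19 above 0 and none called by either adjustment, so 0 adjusted over the list alone. Camera called these 7 lists, at adjusted p from 7.68e-10 for goblet cells to 0.0333 for the antimicrobial list, but with adjusted p = 0.762 with an estimated correlation for colonocytes and adjusted p = 0.71 with an estimated correlation for the other 6. Fry called 1 list, goblet cells. Camera called 16 of 37 lists in all, 1 higher and 15 lower. Over all genes, limma called 46 differences higher and 496 lower. The medians of the housekeeping genes, -1.35, and of the receptor genes, 0.36, were the reverse of their difference in water.

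Quantile normalization gave 0 called differences with limma, with 2073 at an unadjusted p under 0.05, and array medians set equal 26 higher and 539 lower. The count was 3178 without wild-type DSS 1, 198 without wild-type DSS 2, 215 and 177 without Parp1-/- water 2 and 3, and 263, 230 and 237 without Parp1-/- DSS 1, 2 and 3. Without the array labelled wild-type water 1 it was 443. Of 26 called genes considered by name, 6, 4 and 7 were not called without the arrays labelled wild-type water 1, 2 and 3, 0, 9 and 4 without wild-type DSS 1, 2 and 3, 4, 11 and 11 without Parp1-/- water 1, 2 and 3, and 8, 10 and 11 without Parp1-/- DSS 1, 2 and 3. Adamdec1, Slpi and Reg3g were among those lost, and Klk1, Muc2 and Car1 were called without each of the 12 arrays in turn. With the receptor median as a covariate 223 differences were called higher and 338 lower, and 248 of the 542 calls were kept. Of the 26, 4, Adamdec1, Reg3g, Mki67 and Cdk1, were not called, colonocyte genes turned to 0.43 and 5 of the other 6 lists were not called, goblet cells keeping the call. The antimicrobial call was lost without wild-type water 2 (adjusted p 0.0516), wild-type DSS 2 (0.0853), wild-type DSS 3 (0.131) and Parp1-/- water 1 (0.118), and the colonocyte call without wild-type DSS 3 (0.131) and Parp1-/- water 1 (0.11). Quantile normalization lost both calls, and array weights, whose estimation did not converge, the antimicrobial one.

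Across 81 genes of the inflammatory cytokine, neutrophil, interferon and NF-kappaB lists, the DSS responses of the genotypes correlated with Pearson's r of 0.829 and Spearman's rho of 0.775, with a slope of 0.655 of Parp1-/- on wild type. Across the 676 genes of all lists r was 0.463, and across all 21314 genes r was 0.172 and rho 0.0324. These are correlations across genes, which are not independent replicates, and the 2 responses share no arrays. Clca4b and Nos2 were the 2 genes called higher in both genotypes, where independent lists would share 0.178, and none was called lower in both. Over all genes r was 0.242 without wild-type DSS 3, 0.115 without wild-type DSS 1, 0.0818 without Parp1-/- water 1 and 0.120 without Parp1-/- DSS 1.

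**Figure D3:**
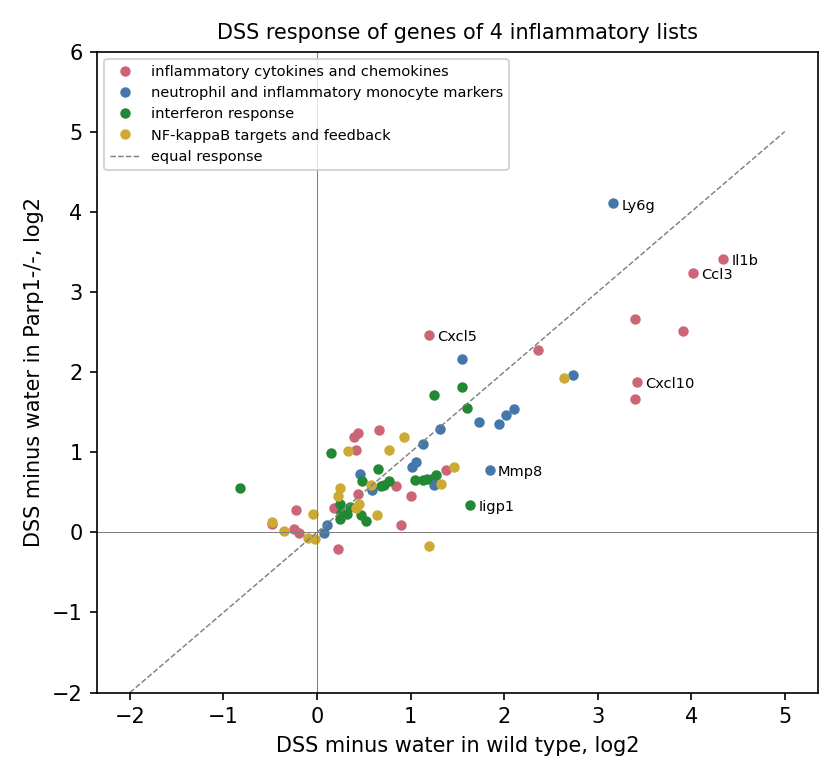
Each point is 1 of 81 genes of the inflammatory cytokine, neutrophil, interferon and NF-kappaB lists, with its log2 DSS response in wild-type mice on the x axis and in Parp1-/- mice on the y axis (3 mice per group), and the dashed line marks equal responses. The points follow a slope of 0.655 with r = 0.829.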

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

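The tests of the technical difference between arrays, of a genotype difference in both treatments and in water alone, of muscle loss with DSS and of both explanations for the neutrophil genes, and the count over all 200 regroupings, were chosen only after the result was seen, and the covariate fit and the fit of 8 arrays were added after seeing the data. Groups of 3 mice were not tested for single arrays that stand apart.

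The DSS response differed between genotypes, by limma's interaction test, in 542 genes, whose values are Parp1-/- minus wild type. The largest positive differences were Slpi at 3.46, Bcr at 2.08, Psme2 at 2.06, Ndufb3 at 1.37, Polg2 at 1.35, Defb3 at 1.24, Ly6k at 1.13 and C8g at 1.125. The largest negative ones were Adamdec1 at -4.64, Reg3g at -3.505, Cnn3 at -3.47, Cox20 at -3.25, Mob1b at -3.16, Acap2 at -3.06, Senp6 at -3.02 and Cct4 at -2.99. Named list members that differed were Klk1 at -2.47, Agr2 at -2.27, Muc2 at -2.19, Cdk1 at -2.72, Mki67 at -1.97, Car1 at -2.04, Clock at -2.05, Nr1d2 at -1.67, Lypd8 at -2.15 and Slc6a14 at -2.52. Camera called 16 of 37 lists for this difference, 1 higher and 15 lower, and those described in the results were goblet cell at -1.24, respiratory chain at -1.08, cell cycle at -1.02, fatty acid oxidation at -1.01, colonocyte at -0.45, antimicrobial at -0.71 and squamous epithelium at 0.37. Each of these lists lost its call with an estimated correlation, with adjusted p = 0.762 with an estimated correlation for colonocytes and adjusted p = 0.71 with an estimated correlation for the others. After quantile normalization limma called 0 genes, with 2073 at an unadjusted p under 0.05. Among probe sets with no gene symbol, which enter no comparison above, 287 were higher and 580 lower with DSS in wild-type mice, and 2 higher and 1 lower in Parp1-/- mice.

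Common genes were lower and receptor genes higher in the wild-type water arrays than in the Parp1-/- water arrays. A genotype difference of similar size in both treatments is argued against for the 3813 genes called higher in water. Their median was 1.49 there but 0.348 in DSS, with quartiles of 0.151 and 0.562. Without wild-type DSS 1, the DSS array that shows the pattern, it was 0.031, with quartiles of -0.107 and 0.158. These genes were picked by their values in water, so some decrease was built in. Wild-type DSS 1 was left out for the same profile, which builds in a further decrease, so the value without it carries little weight. A smaller genotype difference common to both treatments is not excluded. A technical difference of these arrays or their RNA and a genotype difference in water alone cannot be told apart, because all 3 wild-type water arrays share the profile. Wild-type DSS 1 shows it too, which a difference in water alone does not cover, but that is 1 array. The arrays with the profile carry the lowest numbers in the sample titles. What these numbers stand for is not given in the sources used here, and their order was not tested. Across genes, the genotype difference in water correlated with the difference between wild-type DSS 2 and 3 and wild-type DSS 1, at Pearson's r of 0.690 and Spearman's rho of 0.702, but that array was singled out by the same profile, so this decides nothing. With the receptor median as a covariate 459 genes were called in place of 6725. That median was at 0.377 to 0.416 in the wild-type water arrays and -0.116 to -0.008 in the Parp1-/- water arrays. Within groups it varied most in wild-type DSS, from -0.098 to 0.384. The fit therefore cannot separate the covariate from the genotype difference in water, and a lost call does not show that a difference is absent.

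Smooth muscle genes were high in 3 of the 6 Parp1-/- arrays. A loss of muscle expression with DSS cannot be told apart from the spread between mice: the list differed by -0.68, the two-sided exact permutation test gave p = 1, where 3 against 3 mice cannot go below 0.1, and Parp1-/- water 1 was at -0.35 without DSS. An unequal share of muscle wall between the tissue samples is a candidate explanation: across genes outside the list, Parp1-/- water 2 minus water 1 correlated with Parp1-/- DSS 1 minus the mean of DSS 2 and 3, at r = 0.557. Both differences set arrays with high muscle genes against arrays with low ones. Genes that vary with muscle would give a positive r under other explanations too, so r does not decide between them. Enteric neuron and glia markers were higher by 0.70 and 0.77 in the same 2 differences, and endothelium markers by 1.19 and 0.38, while adipocyte markers were at 1.28 and -0.07 and extracellular matrix genes at 1.32 and 0.18. No biological explanation other than DSS was tested.

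Neutrophil genes were lower in Parp1-/- than in wild-type mice after DSS by -0.58. The difference was -0.81 without wild-type DSS 1, the array with the wide spread, with a standard error over arrays of 0.65. That array had a list mean of 0.69, below wild-type DSS 2 and 3 at 1.88 and 0.87. Including it therefore made the difference smaller and not larger. With that standard error, the change without the array does not decide whether its wide spread matters. Leaving out each of the other 5 DSS arrays gave -0.21 ± 0.42 (SE) without wild-type DSS 2 to -0.99 ± 0.38 without Parp1-/- DSS 2. A weaker neutrophil response in Parp1-/- mice may be present, but the two-sided exact permutation test gave p = 0.4, where 3 against 3 mice cannot go below 0.1, so it cannot be told apart from the spread between mice.

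Other splits of the arrays were tested for each count. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. For DSS in wild-type mice 1 of the 10, the real one, reached 2781 genes and the highest other gave 777. For DSS in Parp1-/- mice 2 of 10 gave as many as the real 2 genes, and the highest other gave 169, in the split of Parp1-/- water 1 and DSS 2 and 3 from Parp1-/- water 2 and 3 and DSS 1, the arrays with high smooth muscle genes; that count points to a structure of the samples. For genotype in water 1 of 10 reached 6725 and the highest other gave 0, and for genotype in DSS all 10 gave at least the real 0 and the highest other 12. Averaged over treatments, 4 of 100 drawn regroupings within treatment gave as many as 4801 genes, a share under 0.05, and so did 5 of all 200 regroupings, a share of 0.025. Chance is thus less likely for that count but not excluded, as it was 1 of several counts tested. The highest other regrouping gave more genes, 9319, which points to a structure of the samples. For the difference of responses 7 of 100 reached 542, and 14 of all 200, so chance is not excluded, and the highest other, 6611 of those drawn and 9319 of all, points to a structure of the samples.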

How the results depend on the processing

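The receptor median as a covariate and the fit of 8 arrays were chosen after seeing the data, the other alternatives before the data were examined; the cause of each change below was not tested unless stated. No paired analysis was possible because replicate numbers follow accession order and each mouse has its own label. The filter on dim probe sets was not run and log2(value + 16) did not apply, as the values are centred logs, which also leaves signal over background unknown. Counts are in the order DSS in wild type (2781 in the results), DSS in Parp1-/- (2), genotype in water (6725), genotype in DSS (0), genotype averaged (4801) and difference of responses (542). The probe set rule as planned gave 2686, 6, 6664, 0, 4867 and 498. Quantile normalization gave 232, 85, 2219, 0, 1786 and 0. Array weights gave 8772, 1457, 10771, 6184, 12102 and 7675, but their estimation did not converge, with a weight of 964 for wild-type DSS 2 and 0.0773 to 2.80 for the others. An adjusted p under 0.01 gave 1025, 1, 2429, 0, 939 and 136, by its own construction fewer. The covariate gave 2231, 27, 459, 0, 12 and 561. Because the receptor median did not overlap between the water groups, its losses do not show that a difference is absent. Only the arrays compared gave 641 for DSS in wild type and 9 for DSS in Parp1-/- mice, every probe set on its own gave 9 for the latter, trend and robust options 7 there and 133 for the difference of responses, and the 8 arrays 13 for DSS in Parp1-/- mice. Where limma called 0 genes for genotype in DSS, 261 to 1392 had an unadjusted p under 0.05, and 2073 did for the difference of responses after quantile normalization. All other counts stayed within 1.5 times, namely array medians equal, a 1.5-fold change, and the alternatives not given above for a count. Leaving out 1 array gave 1211 to 6865, 1 to 11, 2948 to 6167, 0 to 2, 1921 to 9133 and 177 to 3178. The correlation of DSS responses over all genes, 0.172, was 0.258 after quantile normalization and 0.0818 to 0.242 without 1 array.

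With the covariate these values changed sign: for DSS in wild type Parp1 to -0.44, Slpi to -0.45, colonocyte genes to -0.007 and respiratory chain genes to -0.07; for DSS in Parp1-/- mice Parp1 to 0.004; for genotype in water Pramel16 to 0.37, Eif4a3l1 to 0.63, Myod1 to 0.21, Mrgpra2b to 0.56, and the cell cycle, cholesterol, fatty acid, tight junction and xenobiotic lists to -0.22, -0.097, -0.022, -0.345 and -0.066; for genotype in DSS respiratory chain genes to -0.022; averaged, Pgd to -0.61, Pramel16 to 0.22, Ppifos to 0.01 and fatty acid genes to -0.033; for the difference of responses Parp1 to 0.44 and colonocyte genes to 0.43. With array weights Parp1 and Slpi turned to -0.10 and -0.192 for DSS in wild type and Parp1 to 0.063 for the difference. Leaving out 1 array turned Parp1 (-0.41 to 0.37) and Slpi (-0.19 to 0.98) for DSS in wild type, Parp1 for DSS in Parp1-/- mice (-0.115 to 0.008), the interferon (-0.525 to 0.056) and smooth muscle (-0.051 to 1.16) lists for genotype in DSS and Parp1 for the difference of responses (-0.42 to 0.36). Klk1, Muc13, Muc2 and Bcr kept their calls for DSS in wild type and for genotype in water, and Clca4b for DSS in both genotypes, under every alternative run for them, which for Muc2 did not include every probe set on its own.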

Other observations

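The circadian genes and sex-linked genes below were looked at after their values were seen, and the test of the genes next to Parp1 was fixed before its result was seen.

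Among clock genes, Npas2, a transcription factor that pairs with the core clock protein Arntl, rose by log2 2.46 ± 0.23 (SE, n = 3 mice per group) in wild-type mice, with a limma adjusted p of 0.000103, and was at 1.73 ± 0.23 in Parp1-/- mice, with an adjusted p of 0.0513. Dbp, a transcription factor driven by the clock, fell in wild-type mice, at -1.48 ± 0.42 with an adjusted p of 0.0409, and was at -1.87 ± 0.42 in Parp1-/- mice, not called. Arntl was at 0.69 ± 0.30 and 1.25 ± 0.30, Per3 at -0.60 ± 0.25 and -0.90 ± 0.25, and Tef at -0.44 ± 0.15 and -0.42 ± 0.15 in wild-type and Parp1-/- mice, none called. The interaction test called none of Dbp (adjusted p 0.755), Per3 (0.675), Tef (0.969) and Npas2 (0.28), but it called Clock, at -2.05 with an adjusted p of 0.00661, and Nr1d2, at -1.67 with 0.00566. Both calls were lost after quantile normalization, which left 0 called differences, and in none of the other alternatives. The housekeeping genes had a median of -1.35 in the same test, so these 2 differences were not set apart from a shift that many genes share. In Parp1-/- mice the circadian list had 7 of 18 members above 0 and a mean of -0.14; 2 members rose, 4 fell adjusted over the list alone, and Nr1d2 was at -0.95. Camera called the list lower at 0.0443, with adjusted p = 0.483 with an estimated correlation, and the call was lost without Parp1-/- water 1 (0.535), Parp1-/- DSS 1 (0.0784) and Parp1-/- DSS 3 (0.106), and in all under 11 of 17 alternatives, among them fry, quantile normalization, the probe set rule as planned, only the arrays compared and the covariate. In wild-type mice Dbp was not called without each of the arrays labelled wild-type water 1, 2 and 3 and wild-type DSS 1 and 2 in turn.

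Xist, the RNA of the inactive X chromosome, was at 5.47 in Parp1-/- water 3 and between -0.18 and 0.45 in the other 11 arrays. The Y-linked genes Kdm5d, Eif2s3y and Uty were at -3.07, -3.19 and -2.79 in Parp1-/- water 3. High Xist with low Y-linked genes is the pattern of a female mouse, so the Parp1-/- water group may mix the sexes. The labels give no sex. In the other 11 arrays Kdm5d, Eif2s3y and Uty ranged from -2.27 to 0.48, from -1.49 to 0.41 and from -1.21 to 0.51, lowest in the array labelled wild-type water 1. That array also had the lowest housekeeping mean, -1.83, and its Xist was only at 0.31. Without Parp1-/- water 3, 1 gene was called for DSS in Parp1-/- mice.

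Expression differences linked to the altered Parp1 locus may reach its neighbours, as a hypothesis. The 40 measured genes nearest to Parp1 had a median absolute genotype difference of 0.126 in the DSS groups without wild-type DSS 1, against 0.108 over 10000 random windows of that size, at percentile 74.2, which leaves the hypothesis undecided. The largest difference among them was Enah at 0.38.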
